A study of Mus musculus with 3 samples.

How the data were processed

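The series holds 3 single-cell RNA libraries of mouse ear skin, 1 for each condition: young WT (4 weeks), adult WT (8 weeks) and adult Lang-DTA (8 weeks). Per the labels, minced ear was digested with collagenase, dispase and DNase, and 4 populations were sorted from a pool of 8 to 10 mice and combined at equal shares. For each library 29,000 cells were loaded to capture 20,000, with 10x Genomics 3' v4 chemistry and sequencing to about 30,000 reads per cell. An imiquimod condition that the protocol text names is not analysed here. The authors deposited, for each library, counts of UMIs per gene and called cell barcode, with no normalization. Per the submitters' processing notes these were made with Cell Ranger 8.01 on GRCm38, and per the file headers the version is 8.0.1. The annotation release, the use of intronic reads and any removal of free RNA are not given in the sources used here. Gene positions were taken from GENCODE M21, in which 30934 of the 31053 gene IDs were found. For 35 symbols carried by more than 1 ID, the most abundant ID was used. The list genes Ccn1 and Ccn2 were read under their older symbols Cyr61 and Ctgf.

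The libraries held 137441575, 128595813 and 124590777 UMIs for young WT, for adult WT and for adult Lang-DTA. Per barcode the median number of genes was 3390, 2974 and 3077.5, and the median mitochondrial share 1.25%, 1.95% and 1.80%. Kept were barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which were 37961 of 40004 (96.4%, 92.8% and 95.6% by library). Doublets were called within each library from simulated doublets (2 per cell, 30 principal components, 50 neighbours), at an expected rate of 0.4% per 1000 barcodes. This rule may also take out cycling cells. Counts were scaled to equal depth and log transformed. The 2000 most variable genes, 40 principal components and 20 neighbours gave the graph for Leiden clustering at resolution 1.0, with no integration of the libraries. Xist, Tsix, Y-linked, mitochondrial and ribosomal protein genes and the genes of the immediate early list were barred from the variable genes. Of 42 clusters, 6 in which at least 50% of the cells were called doublets were left out, and 36 were kept. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

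Clusters were named from 26 marker lists fixed before the data were examined. The scoring rule was chosen after the data had been opened: a mean standardized marker level of at least 0.8, at least 0.4 above the second class and with the second at most 0.6 of it, at least 3 markers detected, and no more leading genes from another class's markers than from its own. A cluster counted as immune with Ptprc, the gene of CD45, at 100 CPM or more, also chosen at that stage. This named 29 clusters and left 7 unnamed. The non-immune unnamed clusters were cluster 10, led by Angptl7, Chad and Mgp (1.75%, 1.59% and 5.89% of cells), and cluster 34, led by cornified envelope genes (0.128%, 0.303% and 0.433%). The smaller unnamed immune clusters were 1 led by Plac8 and S100a9 (4.10%, 1.89% and 3.86% of immune cells) and 1 led by haemoglobin and T cell genes (0.413%, 0.567% and 1.10%). Cells were called male or female from Xist and Y-linked transcripts.

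For each class and library with at least 200 cells, UMIs were summed and expressed per 1,000,000. This left 7 classes for the age comparison and 6 for the genotype comparison. Ratios have exact conditional 95% intervals for counts, and shares of cells exact binomial intervals, but a share of 0 is given with the limit of 3 counts of the total. Where a count was 0, 3 counts were put in its place for the ratio, and the fold is given as at least its lower limit. The ratio, interval and list steps were tested on simulated summed counts of lymphatic cells with known changes. These counts held counting error only, as the intervals assume, so the test does not cover variation between cells. Clustering, naming and doublet calling were not simulated. For genotype, 2-fold changes came out at a median of 0.991 with the interval holding the truth in 93% of genes, and 1.5-fold changes at 0.587. For age the medians were 0.982 (93%) and 0.586 (96%), and the direction was right in 100% of changed genes in both. A list of 15 unchanged genes lay at percentile 93.84 for genotype and 63.14 for age, so that a single percentile under 95 is not unusual.

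Genes named in the text followed a rule fixed beforehand: at least 100 UMIs over both libraries and at least 30 CPM in the higher library, at least 0.05 of the level of the class with the highest level (against free RNA), the same direction by at least 1.25-fold in male-called and female-called cells, and at least 1.5-fold in all cells, ranked by the interval limit nearest 0. The first 12 per direction were named in lymphatic cells, 6 in blood endothelial cells and fibroblasts, and 3 in other classes. Some genes that the rule named are not reported. Other genes are members of fixed lists, given as examples chosen after their values were seen. A list was summarized by the median log2 ratio of its members at 10 CPM or more in either library, if at least 3 reached it, and placed among 10000 random lists matched for abundance in 20 bins. Of the 27 lists, the scavenging macrophage list was not compared, because macrophages had under 200 cells. The third comparison used genes at 50 CPM or more and 100 simulated libraries. The share of free RNA in each class was estimated from the keratinocyte and fibroblast lists, leaving out the fibroblast list in fibroblasts and chondrocytes and the keratinocyte list in keratinocytes. The first estimator, a median over 4 lists, was replaced after its values were seen, because endothelium expresses genes of the macrophage list.

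Alternatives tried were a stricter cell filter (1000 genes, 2000 UMIs, 5% mitochondrial), doublet calls kept, Leiden resolutions 0.5 (32 clusters) and 2.0 (57 clusters), male-called or female-called cells only, the mean of both sexes, cells weighted equally, cells thinned to 3000 UMIs, median-of-ratios scaling, free RNA subtracted, list floors of 0 and 50 CPM, age-axis floors of 20 and 100 CPM, and adult WT counts split at random between the 2 ratios. After the data were seen, leaving out the lymphatic clusters mostly of 1 library, taking Ccl21a, Col4a1 and Apln in each cluster of their class apart, leaving out the cycling clusters of gamma delta T and Langerhans cells, drawing keratinocytes again for the third pattern, and searching lymphatic cells for the unnamed clusters and the smallest classes too were added. No test across mice was made, because each condition is 1 pool in 1 library, and genotype, strain background, age, litter and library cannot be separated. Classes under 200 cells and clusters left unnamed were not compared for genes.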

Results

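Single-cell RNA sequencing was carried out on ear skin of wild-type mice 4 weeks old (young WT), wild-type mice 8 weeks old (adult WT) and Langerin-DTA mice 8 weeks old (adult Lang-DTA). The sample titles give C57BL/6J for both wild-type groups and no background strain for the Langerin-DTA mice. In Langerin-DTA mice, diphtheria toxin A is driven by human Langerin regulatory sequence, chiefly in the Langerhans cells of the epidermis. Langerin is the product of Cd207 in mice. Each condition was 1 library made from a pool of mice: 5 males and 3 females for young WT, 6 males and 4 females for adult WT, and 4 males and 6 females for adult Lang-DTA. Lymphatic endothelial cells (CD45-negative, CD31 and podoplanin positive), blood endothelial cells (CD45-negative, CD31 positive, podoplanin negative), CD45-positive leukocytes and cells with neither CD45 nor CD31 were sorted and mixed in equal parts before loading. There were no replicate libraries, so no test was made. The 95% intervals given are exact counting intervals and hold counting error only, not differences between mice or between pools.

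The deposited matrices held 12864 cell barcodes for young WT, 13600 for adult WT and 13540 for adult Lang-DTA, with medians of 9568, 7966 and 8189 unique molecular identifiers (UMIs) per barcode. After filtering, 12399, 12621 and 12941 cells were kept, of which 638, 687 and 701 were called doublets and left out. Clusters were named from marker genes. The largest classes, with young WT first, adult WT second and adult Lang-DTA last, were lymphatic endothelial cells (4062, 1768 and 2790 cells), blood endothelial cells (1801, 3519 and 2622), keratinocytes (1468, 2725 and 3000) and gamma delta T cells (1299, 1348 and 1184). Smaller classes were chondrocytes (651, 359 and 603), fibroblasts (271, 472 and 370), Langerhans cells (550, 393 and 0), and pericytes or smooth muscle cells (284, 131 and 97), with macrophages, cells named migratory dendritic, melanocytes and Schwann cells under 200 cells in every library. At coarser clustering no cluster was named chondrocyte, because the cluster with the highest chondrocyte score (856, 548 and 1323 cells) had a chondrocyte score of 3.05 and a fibroblast score of 1.95, too close for the naming rule. Gene levels are given as counts per 1,000,000 summed UMIs of a class in a library (CPM). Because the sorted populations were mixed in equal parts, shares of classes were compared only inside the CD45-positive clusters, and shares of lymphatic clusters are given within lymphatic cells.

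Langerhans cells, which carry antigen from the epidermis to lymph nodes through dermal lymphatic vessels, were present in both wild-type libraries and absent as a class from adult Lang-DTA. They made up 18.9% of immune cells in young WT (550 of 2905; 17.5 to 20.4%) and 14.9% in adult WT (393 of 2644; 13.5 to 16.3%), against 0 of 1918 immune cells in adult Lang-DTA, which allows a share of up to 0.156% (3 counts of the total). Cd207 itself (ENSMUSG00000034783, chromosome 6: 83671215 to 83677857, GRCm38) was at 3064 CPM in young and 2972 CPM in adult WT Langerhans cells. The cluster named migratory dendritic, led by Ccr7 and also by Mgl2, held Cd207 at 85.4 CPM in young WT, 535 CPM in adult WT and 61.4 CPM in adult Lang-DTA. At least 1 Cd207 UMI was present in 15.3%, 38.5% and 10.1% of its cells, which were a mixture, as finer clustering below shows.

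**Figure D1:**
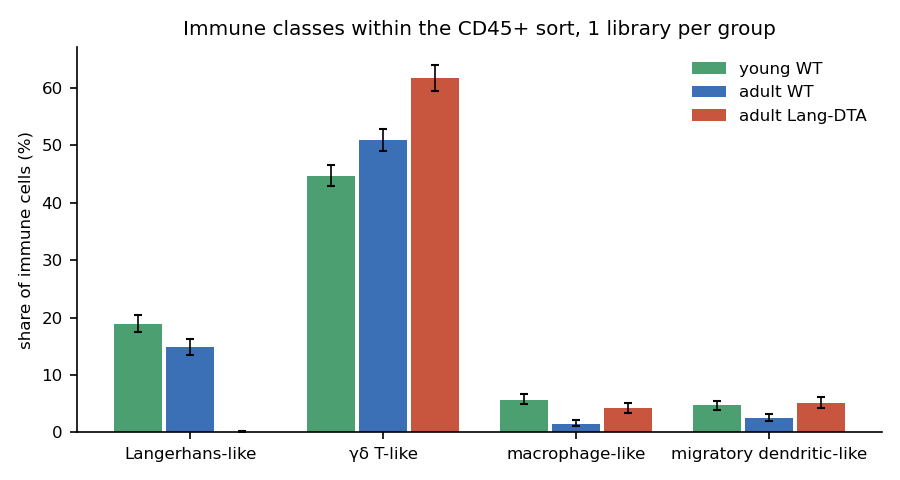
Share of immune cells (percent, linear axis) taken by each named immune class in the 3 libraries, with coloured bars for the share and black lines for its 95% exact binomial interval. Langerhans cells fill 18.9% and 14.9% of the immune cells of the wild-type libraries and none of the 1918 immune cells of adult Lang-DTA.

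Among the other immune classes, gamma delta T cells, the class that holds the dendritic epidermal T cells of mice, made up 44.7% (42.9 to 46.5%) of immune cells in young WT, 50.98% (49.1 to 52.9%) in adult WT and 61.7% (59.5 to 63.9%) in adult Lang-DTA. With Langerhans cells taken out of the total, the shares were 55.2%, 59.9% and 61.7%. Macrophages made up 5.71% (4.90 to 6.62%), 1.55% (1.12 to 2.10%) and 4.17% (3.32 to 5.17%), or 7.05%, 1.82% and 4.17% without Langerhans cells in the total. The cluster named migratory dendritic made up 4.72% (3.97 to 5.55%), 2.46% (1.90 to 3.12%) and 5.16% (4.22 to 6.25%), or 5.82%, 2.89% and 5.16% without Langerhans cells in the total. At finer clustering it separated into a cluster led by Ccr7 (19, 9 and 39 cells; 0.658%, 0.341% and 2.05% of immune cells), which kept the name, and a cluster led by Mgl2 and Cd209d (100, 45 and 42 cells; 3.46%, 1.71% and 2.21%), named conventional dendritic type 2. At coarser clustering the cells named migratory dendritic made up 0.654%, 0.340% and 2.03%. Immune clusters that the marker rule left unnamed took 25.9%, 30.1% and 28.9%. Among these were a cluster led by Il7r, Il23r and Icos (6.47%, 14.3% and 7.40%), a cluster led by Lyz1, Ccr2 and Mgl2 (12.7%, 3.97% and 7.66%) and a cluster led by Ccl5, Trac and Gzma (2.24%, 9.46% and 8.92%).

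The first comparison asked how lymphatic endothelium of adult WT ears differed from that of young WT ears. Cell cycle genes and extracellular matrix genes were lower in adult WT, whereas the chemokine Ccl21a, the transcription factor Hes1, and the interferon, MHC class I and glucocorticoid response genes were higher. Mki67, the proliferation marker, was at 56.5 CPM in young and 2.70 CPM in adult WT lymphatic cells (log2 ratio -4.38), and Top2a, the topoisomerase of replicating cells, at 44.5 and 4.67 CPM (-3.25). Ccl21a, the chemokine that guides dendritic cells bearing Ccr7 into lymphatic vessels, was at 4328 CPM in young and 9964 CPM in adult WT (1.20). Lymphatic cells also sat in different clusters by age. Cluster 2, led by Lyve1, Reln and Ccl21a, held 39.3% of young and 60.6% of adult WT lymphatic cells, and cluster 4 held 42.0% and 20.7%. Inside cluster 2 Ccl21a was at 6577 and 13082 CPM, inside cluster 4 at 3357 and 7685 CPM and inside cluster 13 at 1867 and 2247 CPM. This split was chosen after the data were seen. Reads of near-identical gene copies of Ccl21a may have been counted with it, which was not checked. Among the markers of lymphatic endothelium, Prox1 (1240 and 1171 CPM) and Lyve1 (2478 and 2447 CPM) were at close levels, whereas Ccl21a and Reln were higher in adult WT.

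The fixed gene lists were compared with 10000 random lists of genes matched for abundance, which describes these libraries only. Members of the random lists were drawn independently, whereas genes of a fixed list may move together. A list of such genes can therefore lie beyond all random lists more easily. The median log2 ratio of the proliferation list was -2.10 (14 genes measured), below all 10000 random lists. With the cells of clusters 5 and 28, described with the next comparison, left out, the median was -0.57, Mki67 was at 5.23 and 0.63 CPM, and Top2a at 4.50 and 2.52 CPM. The median was -1.37 with doublet calls kept, -1.35 with cells weighted equally and -0.35 for genes at 50 CPM or more. The list of fibrillar matrix genes had a median of -0.90 and the list of basement membrane genes -0.56, both below all 10000 random lists (fibrillar matrix -0.57 with no CPM floor). Fibronectin (Fn1) was at 425 CPM in young and 169 CPM in adult WT, the type IV collagen chains Col4a1 and Col4a2 at 590 and 285 CPM and at 273 and 127 CPM, and laminin Lamb1 at 261 and 122 CPM. Endothelial junction genes had a median of -0.29 (percentile 1.98), and of -0.17 with median-of-ratios scaling.

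Higher in adult WT lymphatic cells were the immediate early and dissociation stress list (median 0.44) and the interferon response list (0.41), both above all 10000 random lists (0.29 for immediate early genes in female-called cells, 0.22 for interferon genes in male-called cells), the glucocorticoid response list (0.38, percentile 99.96) and the MHC class I list (0.31, percentile 99.97). Examples were the immediate early gene Fos (5931 and 8338 CPM), the interferon-induced GTPase Gbp4 (3.85 and 14.9 CPM), the glucocorticoid-induced Tsc22d3 (66.7 and 107 CPM), and B2m, the light chain of MHC class I (205 and 333 CPM). The lymphatic capillary identity list had a median of 0.07 (percentile 85.5), the collector and valve list -0.18 (11.7), the lymphangiogenic receptors and regulators -0.19 (5.62), the lymphangiogenic ligands 0.16 (96.3), and the leukocyte trafficking list 0.01 (86.7). The median was -0.38 for cholesterol synthesis (percentile 2.73), -0.21 for the TGF-beta response (6.91), -0.07 for Notch signalling (54.8), -0.05 for hypoxia and glycolysis (67.8), 0.02 for NF-kB and inflammatory cytokines (85.4) and 0.03 for the circadian clock (91.9). Only 1 gene of the MHC class II list reached 10 CPM, and the list's summed level was 26.5 CPM in young and 31.6 CPM in adult WT. The median gene of lymphatic cells lay at -0.10, and median-of-ratios scaling moved every ratio of this comparison by 0.112. The directions of the proliferation, matrix, interferon, immediate early, glucocorticoid and MHC class I lists were the same relative to that shift. Some lists of other cell types were also higher in adult WT lymphatic cells, with keratinocyte genes at 36.0 and 106.4 CPM and erythroid genes at 82.2 and 205.0 CPM. Fibroblast genes (41.3 and 38.3 CPM) and cartilage and muscle genes (1.2 and 0.7 CPM) were not. Median UMIs per lymphatic cell were 7114.5 and 4321, and the estimated free RNA share 0.889% and 1.208%.

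The genes named by the fixed rule as highest in adult over young WT lymphatic cells, apart from genes with the same shift in every class, were Fxyd1, a regulator of the sodium pump (14.1 and 90.4 CPM; log2 ratio 2.68), the interferon-induced GTPase Iigp1 (14.7 and 85.6 CPM; 2.55), Mapt, which codes for tau (15.8 and 68.0 CPM; 2.10), the Notch target Hes1 (458 and 1754 CPM; 1.94), the protease inhibitor Serpina3n (12.2 and 46.7 CPM; 1.94), the heat shock gene Hspa1a (9.51 and 32.8 CPM; 1.79), Lst1 (9.51 and 30.4 CPM; 1.68) and Ackr2, the scavenging chemokine receptor of lymphatic endothelium (24.5 and 76.4 CPM; 1.64, 1.49 to 1.80). Those named as lowest included the imprinted transcript H19 (43.7 and 4.30 CPM; -3.35), the RNA-binding protein Igf2bp3 (30.9 and 6.02 CPM; -2.36) and the growth factor Igf1 (58.6 and 13.4 CPM; -2.13). Also named were the cycling genes Mki67, Top2a, Hist1h2ap (-2.98), Cenpf (-2.85) and Hist1h1b (-2.56), the endothelial receptor Cd93 (77.0 and 20.9 CPM; -1.88), Serpinb6b (-2.01) and the adhesion gene Sdk1 (-1.81). Nmt1 (15.5 and 78.0 CPM), Atp5k (38.0 and 141 CPM), Btg1 (315 and 789 CPM) and Pabpc4 (26.6 and 76.4 CPM) were higher and Il31ra (379 and 91.9 CPM) lower in adult WT in all 7 classes compared, so that they were not particular to lymphatic cells.

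**Figure D2:**
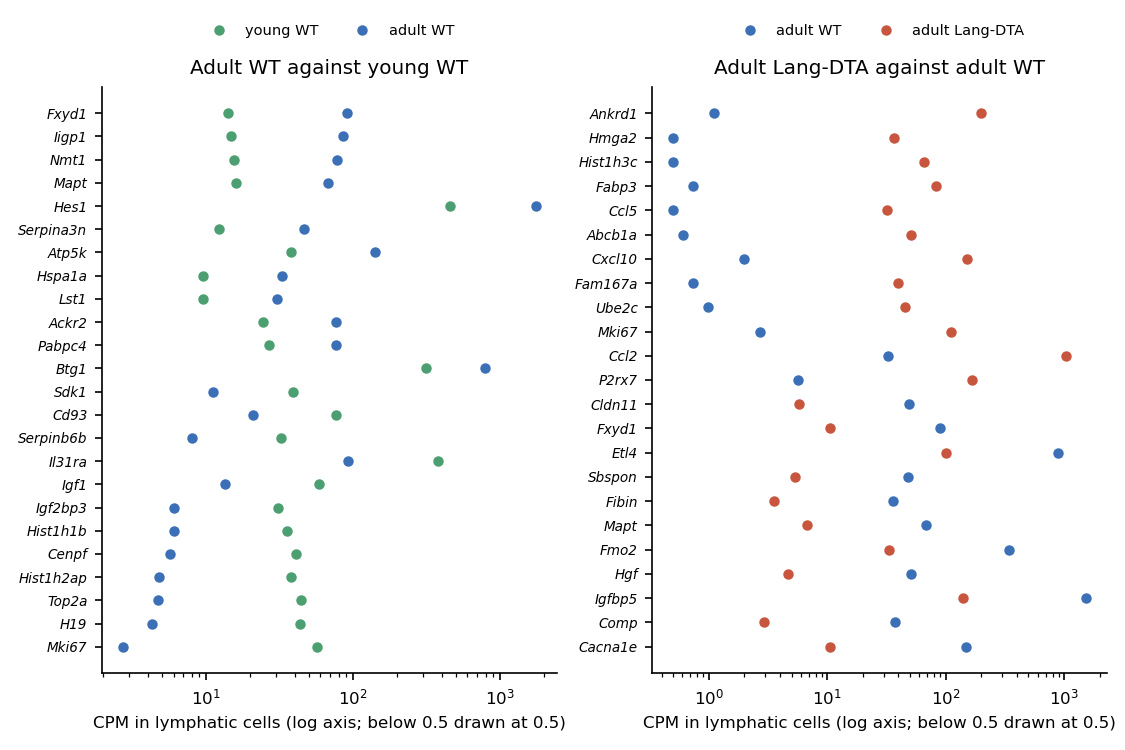
Reported genes that the fixed rule named in lymphatic endothelial cells (CPM on a log axis; values below 0.5 drawn at 0.5), with adult WT against young WT on the left and adult Lang-DTA against adult WT on the right, 1 point per library. Hes1 lies at 458 CPM in young and 1754 CPM in adult WT, and Fmo2 at 343 CPM in adult WT and 33.1 CPM in adult Lang-DTA.

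Matrix genes were also lower in other stromal classes and in keratinocytes of adult WT. The basement membrane list had a median of -0.64 in blood endothelial cells, -0.94 in chondrocytes, -0.52 in fibroblasts and -0.57 in keratinocytes, and the fibrillar matrix list -0.97 in blood endothelial cells, -0.77 in chondrocytes and -0.39 in fibroblasts, all below all 10000 random lists. With no CPM floor the fibrillar matrix median of blood endothelial cells was -0.40. In blood endothelial cells, Col4a1 was at 748 CPM in young and 308 CPM in adult WT and elastin (Eln) at 542 and 239 CPM, while Hes1 was at 174 and 575 CPM. Their Notch list was lower (median -0.39, percentile 0.01), with the Notch target Hey1 at 89.2 and 48.4 CPM. The rule also named Sectm1b (10.3 and 32.6 CPM), Slc8a1 (119 and 45.3 CPM) and Htra1 (50.7 and 19.1 CPM) in this class and, with the same direction in every class, Nmt1, Atp5k, Btg1, Nsa2, Il31ra and Lars2 (1275 and 440 CPM).

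Proliferation genes were lower in adult WT leukocytes of the epidermis, with a median of -2.23 in gamma delta T cells and -3.24 in Langerhans cells, both below all 10000 random lists. With doublet calls kept, the median in Langerhans cells was -0.96. Much of this lay in small clusters of cycling cells: cluster 31 held 11.6% of gamma delta T cells in young and 1.86% in adult WT, and cluster 41 held 5.45% and 0.254% of Langerhans cells. With these left out, a setting chosen after the data were seen, the medians were -0.42 and -0.61. Mki67 was at 370 and 50.98 CPM in gamma delta T cells and at 249 and 55.4 CPM in Langerhans cells. In Langerhans cells the MHC class I and class II lists lay near 0 (medians 0.02 and -0.03), the NF-kB list at -0.25 (percentile 0.69; 0.01 in female-called cells), H2-M5 at 221 and 726 CPM, and Sgcz, a sarcoglycan gene, at 21.5 and 117 CPM. Gamma delta T cells had higher immediate early genes (median 0.40) and a higher Kcnt2, a potassium channel gene (78.0 and 257 CPM).

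Keratinocytes of adult WT had higher MHC class I genes (median 0.69, above all 10000 random lists), with B2m at 182 and 420 CPM and H2-K1 at 154 and 324 CPM. Peptide YY (Pyy) was at 4.42 and 95.6 CPM and the steroid dehydrogenase Akr1c18 at 7.56 and 53.7 CPM, with lower log2 ratios in male-called cells (2.65 and 1.65) than in all cells (4.44 and 2.83). At finer clustering, a keratinocyte cluster that Pyy helps to lead held 169 young and 684 adult WT cells. The class held 1468 and 2725 cells at the main clustering, and levels inside its clusters were not compared. Fibroblasts had higher interferon genes (median 0.37, percentile 99.94; 0.19 for genes at 50 CPM or more), including Gbp2 (12.3 and 62.4 CPM) and the chemokine Cxcl10 (14.8 and 83.3 CPM). They also had more complement C7 (1 and 319 UMIs; 232-fold, 41.3 to 9191; log2 ratio 1.06 in female-called cells) and more myocilin (Myoc, 122 and 461 CPM), and less H19 (146 and 20.7 CPM) and less Cthrc1, a collagen-associated secreted protein (369 and 142 CPM). Chondrocytes, which form the elastic cartilage of the ear, had lower cholesterol synthesis genes (median -0.998; Hmgcs1 292 and 138 CPM) and less Igfbp2 (127 and 20.1 CPM), with higher interferon genes (0.95; 0.50 in female-called cells), Ibsp, which codes for bone sialoprotein (1.95 and 142 CPM), and Prg4, which codes for lubricin (82.4 and 482 CPM).

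The second comparison asked how adult skin without Langerhans cells differed from adult skin with them. The widest difference lay in lymphatic endothelium, where immediate early genes, the chemokine Ccl21a and the guidance protein Reln were lower in Lang-DTA and MHC class I and interferon genes were higher. The interquartile range of log2 ratios across genes was 1.01 in lymphatic cells, against 0.141 in keratinocytes, 0.163 in gamma delta T cells, 0.185 in blood endothelial cells, 0.231 in chondrocytes and 0.268 in fibroblasts. For the age comparison the same range ran from 0.291 in blood endothelial cells to 0.433 in chondrocytes, with 0.368 in lymphatic cells. Log2 ratios computed from male-called and from female-called lymphatic cells, which come from different mice of the pools, correlated at 0.963 across genes for genotype and 0.845 for age, genes not being independent replicates. For genotype the same correlation was 0.737 in blood endothelial cells, 0.442 in keratinocytes, 0.293 in fibroblasts, 0.214 in gamma delta T cells and 0.211 in chondrocytes. Both sexes of a pool were sorted and run together, so a trait of that sort or library would give the same agreement. The correlation also depends on the spread of the ratios and on cell numbers. It therefore does not rank the classes by how well their differences repeat. In lymphatic cells the genotype ratios also differed by transcript length, with a median of 0.355 for the shortest 315 genes and -0.173 for the longest 315. That gap was 0.528 (0.324 with clusters 5 and 28, described next, left out), against 0.025 to 0.119 in the other 5 classes. Median UMIs per lymphatic cell were 7114.5 in young WT, 4321 in adult WT and 7787 in adult Lang-DTA. In the other 5 classes they were lower in Lang-DTA than in adult WT (7440.5 against 8622 in blood endothelial cells). The free RNA share estimated in lymphatic cells was 0.889%, 1.208% and 0.557%. With cells thinned to 3000 UMIs the genotype interquartile range of lymphatic cells was 0.908.

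**Figure D3:**
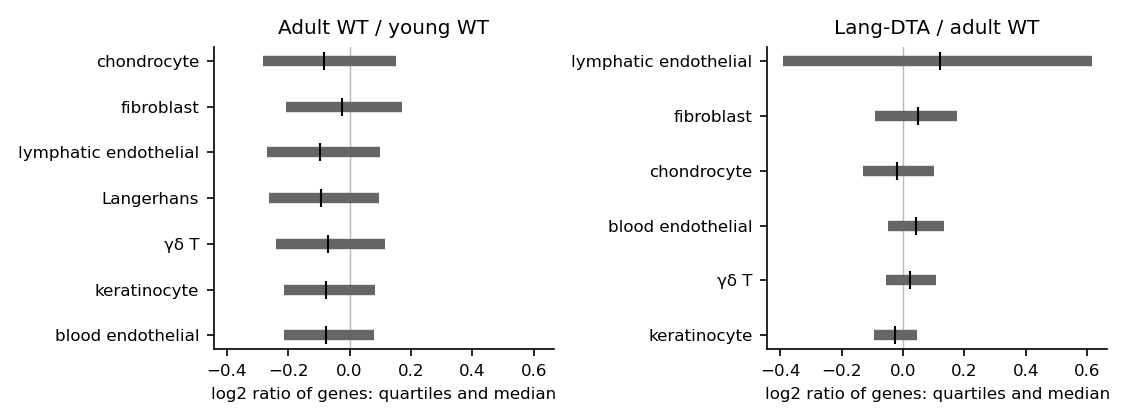
Log2 ratios across genes (linear axis) for each cell class, adult WT over young WT on the left and adult Lang-DTA over adult WT on the right, with grey bars from the lower to the upper quartile and black marks at the median. The bar of lymphatic cells spans 1.01 for genotype, whereas those of the other classes span 0.141 to 0.268.

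Lymphatic cells of the libraries sat in different clusters. Clusters 2, 4 and 13 held 39.3%, 42.0% and 14.1% of young WT and 60.6%, 20.7% and 15.8% of adult WT lymphatic cells, but 10.3%, 7.06% and 2.19% of those of adult Lang-DTA. Cluster 5 held 74.4% of adult Lang-DTA lymphatic cells (2075 of 2790), against 2.38% in adult WT and 2.76% in young WT. It was led by Gdf15, Ccl2, Gpnmb, Olfm1, Ankrd1, Cd63, Angpt2 and Pgf, and none of its first 10 genes was a marker of the class. It was named by its mean marker score (lymphatic 1.67, erythroid 0.609). At finer clustering, a cluster with the same first 4 genes held 1128 adult Lang-DTA, 3 adult WT and 2 young WT cells and was left unnamed, because its lymphatic score (1.41) and erythroid score (1.12) were too close. Cluster 28, of cycling cells led by histone genes, Top2a and Mki67, held 6.06% in adult Lang-DTA, 0.509% in adult WT and 1.80% in young WT. A cluster drawn mostly from 1 library may stand for that library, and these leading genes are not given as results. Values are therefore also given for the shared clusters alone, with clusters 5 and 28 left out (1717 adult WT and 546 adult Lang-DTA cells), a setting chosen after the clusters were seen. The interquartile range of log2 ratios was then 0.476. The clusters were made without immediate early genes, whereas identity genes were not barred. Leaving clusters out tends to shrink differences in genes that set the clusters apart. Those lists therefore cannot be ranked against each other by this setting.

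Ccl21a was at 9964 CPM in adult WT and 2478 CPM in adult Lang-DTA lymphatic cells (log2 ratio -2.01), and at 9999 and 4595 CPM in the shared clusters (-1.12). Inside cluster 2 it was at 13082 and 6742 CPM and inside cluster 4 at 7685 and 2953 CPM, but inside cluster 13 at 2247 and 3400 CPM. Reln was at 1673 and 394 CPM (-2.09; -1.08 in the shared clusters). Immediate early genes had a median of -1.14, below all 10000 random lists, and -1.11 in the shared clusters, with Fos at 8338 and 3536 CPM (-1.24 and -1.19), Egr1 at 1803 and 686 CPM (-1.39 and -1.35) and Ier3 at 1100.2 and 229.5 CPM (-2.26 and -2.12). MHC class I genes had a median of 0.81 (percentile 99.8; 0.50 in the shared clusters), with B2m at 333 and 1339 CPM (2.01 and 1.06) and H2-K1 at 179 and 436 CPM (1.29 and 0.92). Interferon response genes had a median of 1.11 (percentile 99.99; 0.58 in the shared clusters), with Isg15 at 46.0 and 150.1 CPM (1.71 and 1.29) and Bst2 at 150 and 401 CPM (1.42 and 1.03).

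Genes of lymphatic identity were lower over all lymphatic clusters and less so in the shared ones. The capillary identity list had a median of -0.93 (percentile 0.09) and -0.14 (percentile 13.6) in the shared clusters, and the collector and valve list -0.89, below all 10000 random lists, and -0.12 in the shared clusters. Prox1, the master transcription factor of lymphatic fate, was at 1171 and 777 CPM (-0.59; -0.11 in the shared clusters), Lyve1 at 2447 and 1309 CPM (-0.90; -0.42), Flt4, the receptor for Vegfc, at 373 and 172 CPM (-1.12; -0.02) and Foxp2 at 498 and 83.6 CPM (-2.58; -0.77). The median of the lymphangiogenic receptors and regulators was -0.55 and turned to 0.20 in the shared clusters, and that of the leukocyte trafficking list was -0.45 and turned to 0.01. Notch genes had a median of -0.82 (percentile 0.40; -0.20 in the shared clusters), with the ligand Dll4 at 114 and 26.99 CPM. Endothelial junction genes had a median of 0.36 (percentile 84.0; 0.35 in the shared clusters).

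Matrix genes of lymphatic cells were higher in adult Lang-DTA when the shared clusters were compared. The fibrillar matrix list had a median of 0.33 (percentile 78.0; -0.23 with doublet calls kept) and of 0.96, above all 10000 random lists, in the shared clusters, and the basement membrane list -0.15 (18.8) and 0.49 (99.9). In the shared clusters Fn1 was at 171 and 338 CPM, Col4a1 at 285 and 625 CPM, Col4a2 at 127 and 302 CPM and the adhesion molecule Vcam1 at 3.02 and 18.8 CPM. The lists that served as a check on free RNA moved there as well, the erythroid median from -0.81 over all clusters to 1.23 and the keratinocyte median from -0.99 to -1.41. Proliferation genes had a median of 4.18, above all 10000 random lists, and of 0.89 in the shared clusters. Over all clusters it was 2.93 with doublet calls kept and 1.81 for genes at 50 CPM or more. Circadian clock genes had a median of 1.15 over all clusters, above all 10000 random lists, and of -0.45 in the shared ones, with Nr1d1 at 21.5 and 290 CPM over all and at 21.7 and 21.2 CPM in the shared clusters. The NF-kB list had a median of 0.23 (73.8) and of -0.66 in the shared clusters, and glucocorticoid response genes -0.36 (4.38) and -0.92. Medians of the other lists were 0.41 for cholesterol synthesis (83.6), 0.40 for lymphangiogenic ligands (75.7), 0.31 for hypoxia and glycolysis (80.8) and -0.12 for the TGF-beta response (19.7). The summed level of the MHC class II list was 31.6 and 43.0 CPM.

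**Figure D4:**
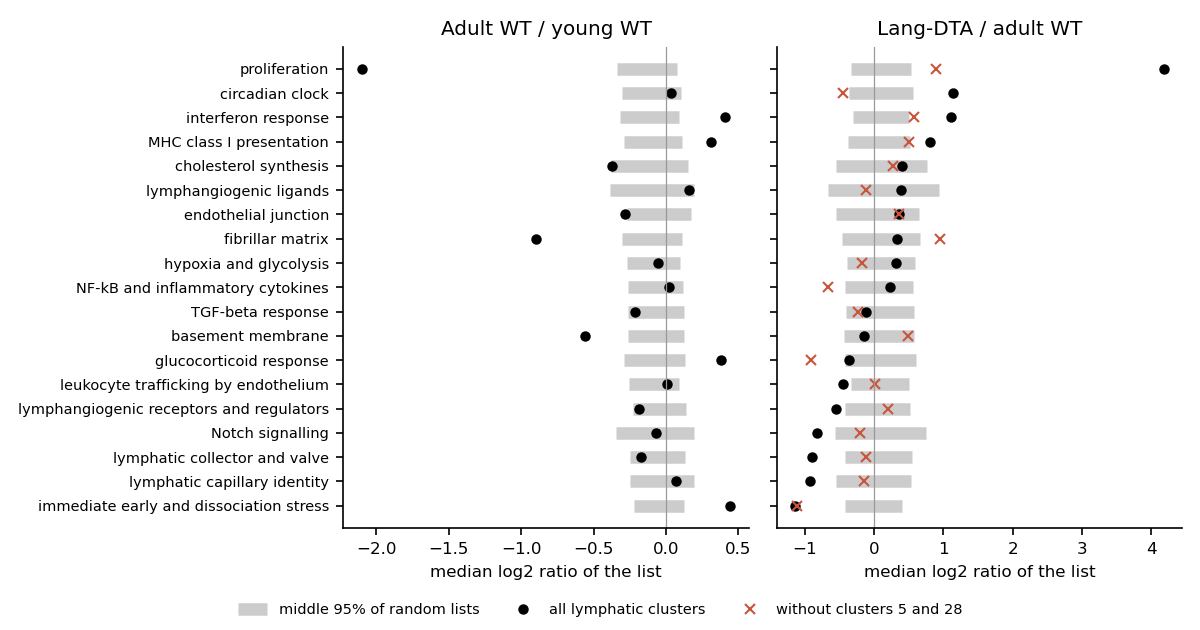
Median log2 ratio of each fixed gene list in lymphatic endothelial cells (linear axis), adult WT over young WT on the left and adult Lang-DTA over adult WT on the right; black points hold all lymphatic clusters, red crosses leave out clusters 5 and 28, and grey bars span the middle 95% of 10000 matched random lists. The immediate early list lies at -1.14 with and -1.11 without those clusters in adult Lang-DTA, and the capillary identity list at -0.93 and -0.14. Immediate early genes were barred from the clustering, so these values do not contrast the lists.

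Among the genes that the fixed rule named as lowest in adult Lang-DTA lymphatic cells, several were also lower by over 2-fold in the shared clusters. These were Fmo2, a flavin monooxygenase (343 and 33.1 CPM; -3.37, and -3.46 in the shared clusters), Mapt (68.0 and 6.71 CPM; -3.34 and -2.82), Etl4 (893 and 100.03 CPM; -3.16 and -2.39), the calcium channel gene Cacna1e (148 and 10.6 CPM; -3.81 and -2.17), Fxyd1 (90.4 and 10.6 CPM; -3.10 and -1.78), the cartilage matrix gene Comp (37.2 and 2.92 CPM; -3.67 and -1.47), Fibin (35.6 and 3.58 CPM; -3.32 and -1.10), the growth factor Hgf (50.6 and 4.69 CPM; -3.43 and -1.07) and Igfbp5 (1543 and 141 CPM; -3.45 and -1.04). For Sbspon and Cldn11 the ratios were -3.16 and -3.09 over all and -0.60 and -0.62 in the shared clusters. Of those named as highest, Ankrd1, Ccl2, Hist1h3c and Mki67 belong to the genes leading clusters 5 and 28. The fatty acid binding protein Fabp3 (0.74 and 83.4 CPM), the ATP receptor P2rx7 (5.65 and 167 CPM), the drug exporter Abcb1a (0.61 and 50.6 CPM), Fam167a (0.74 and 39.6 CPM), the cell cycle gene Ube2c (0.98 and 45.6 CPM) and the interferon-induced chemokine Cxcl10 (1.97 and 150 CPM) were higher over all clusters. In the shared clusters Fabp3 stood at 6 and 3 UMIs, P2rx7 at 45 and 25, Abcb1a at 5 and 6, Fam167a at 6 and 4, Ube2c at 4 and 3 and Cxcl10 at 1 and 0. The shared clusters held 7940777 UMIs in adult WT and 3401406 in adult Lang-DTA, so equal counts would mean a higher level in adult Lang-DTA. Of 48 ratios of genes named in lymphatic cells, over both comparisons, 0 reversed in this setting. Over all clusters Hmga2 had 2 UMIs in adult WT and 883 in adult Lang-DTA (148-fold, 40.8 to 1223) and Ccl5 had 0 and 780, at least 70.6-fold higher, against 2 and 8 UMIs and 0 and 3 UMIs in the shared clusters.

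In blood endothelial cells the monocyte chemokine Ccl2, also a leading gene of lymphatic cluster 5, was at 1.21 CPM in adult WT and 66.1 CPM in adult Lang-DTA (log2 ratio 5.77). Cells of that cluster among them were not looked for. Blood endothelial cells of adult Lang-DTA also had more of the neutrophil chemokine Cxcl2 (11.6 and 52.6 CPM; 2.18), the angiogenic peptide apelin (Apln, 59.5 and 199 CPM; 1.74), Nudt4 (74.5 and 168 CPM) and the actin-bundling gene Fscn1 (44.4 and 98.5 CPM). Their basement membrane list had a median of 0.33, above all 10000 random lists, with Col4a1 at 308 and 672 CPM (1.13), Col4a2 at 210 and 429 CPM and Nid2 at 19.3 and 38.4 CPM. Blood endothelial cells also sat in different clusters by library, with cluster 9, which Apln and Col4a1 help to lead, holding 14.5% of them in young WT, 13.2% in adult WT and 20.7% in adult Lang-DTA. Inside cluster 9 Col4a1 was at 1269 CPM in adult WT and 2080 CPM in adult Lang-DTA and Apln at 102 and 608 CPM. Inside clusters 1, 6 and 8 Col4a1 was at 119 and 155, 404 and 609, and 249.5 and 356 CPM, a split by cluster chosen after the data were seen. Interferon genes were higher too (median 0.21, above all 10000 random lists; 0.12 in female-called cells). Lower were coagulation factor V (F5, 72.2 and 38.9 CPM; -0.89), Sectm1b (-0.99), Rcan1 (-0.69), Mctp1 (-0.64), Tagln (-0.62) and Adgrg3 (-0.65).

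Fibroblasts of adult Lang-DTA had higher interferon genes (median 0.44, above all 10000 random lists), with Ifit1 at 3.99 and 42.6 CPM and the RNA sensor Ifih1 at 32.9 and 85.2 CPM. They also had more Ptx3, a secreted pattern recognition protein (21.1 and 65.3 CPM), heme oxygenase Hmox1 (28.7 and 82.5 CPM), Anxa3 (33.7 and 89.7 CPM), Ifi27l2a (30.9 and 82.5 CPM) and the alarmin Il33 (14.95 and 42.3 CPM). Lower were Slc26a7 (36.3 and 9.06 CPM), Gldn, Col25a1, Rxfp1 (-1.39; -0.05 with doublet calls kept) and Cyp26b1, which breaks down retinoic acid (327 and 152 CPM). Their basement membrane list had a median of 0.27 (percentile 99.94). Fibroblasts also sat in different clusters by library, with cluster 26 holding 166 of 472 in adult WT and 92 of 370 in adult Lang-DTA. The unnamed cluster 10 had its highest score for fibroblasts (2.026, against 1.402 for chondrocytes). It held 205 cells in young WT, 189 in adult WT and 720 in adult Lang-DTA, which are outside the fibroblast comparisons. At finer clustering a fibroblast cluster that Gldn helps to lead held 32 adult WT and 13 adult Lang-DTA cells. Levels inside the fibroblast clusters were not compared.

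In gamma delta T cells, MHC class I genes had a median of 0.31, above all 10000 random lists (H2-K1 368 and 526 CPM), and interferon genes 0.20 (percentile 99.82), against 0.19 and 0.003 in male-called cells. Proliferation genes had a median of -0.91 there, with Top2a at 74.1 and 31.5 CPM and Stmn1 at 83.2 and 42.8 CPM, which turned to 0.15 with doublet calls kept and was -0.08 with the cycling cluster 31 left out (25 adult WT and 12 adult Lang-DTA cells). Grcc10 (0.67), Alpk2 (0.61) and Gstp1 (0.59) were higher. In keratinocytes Spink5, a protease inhibitor of the skin barrier, was at 84.7 and 129 CPM (0.61; 0.21 with cells weighted equally), Npl at 79.2 and 122 CPM and Taco1 at 61.6 and 39.0 CPM. Their MHC class II list had a median of -3.09, with the invariant chain Cd74 at 22.0 and 2.58 CPM and H2-Aa at 11.3 and 1.26 CPM. In chondrocytes, Ibsp (142 and 35.3 CPM), the transferrin gene Trf (379 and 205 CPM) and S100a4 (459 and 262 CPM) were lower and Igfbp2 (20.1 and 56.9 CPM; log2 ratio 0.34 with cells weighted equally), ceruloplasmin (Cp, 19.2 and 60.8 CPM) and Enpp2 (98.1 and 178 CPM) were higher, with cholesterol synthesis genes at a median of -0.32 (-0.08 in male-called cells).

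The third comparison asked whether genes that were higher in young than in adult WT were also higher in adult Lang-DTA than in adult WT. In blood endothelial cells, the type IV collagen Col4a1 was at 748 CPM in young WT, 308 CPM in adult WT and 672 CPM in adult Lang-DTA, and inside their cluster 9 at 3059, 1269 and 2080 CPM. In lymphatic cells Col4a2 was at 273, 127 and 290 CPM, Fn1 at 425, 169 and 368 CPM, Fxyd1 at 14.1, 90.4 and 10.6 CPM and Mapt at 15.8, 68.0 and 6.71 CPM. Reln was at 1246, 1673 and 394 CPM and Ccl21a at 4328, 9964 and 2478 CPM, in adult Lang-DTA below both wild types. Both ratios share the adult WT library, so its counting error links them, as would any other trait of that library. Adult WT lymphatic cells had median UMIs of 4321, against 7114.5 in young WT and 7787 in adult Lang-DTA. The simulations below hold counting error only. Splitting the counts and crossing the sexes keep that library in both ratios, so such a trait cannot be excluded.

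Across 4088 genes of lymphatic cells, log2(young/adult WT) and log2(adult Lang-DTA/adult WT) had a correlation of 0.215 and a covariance of 0.066, against 0.13 and 0.003 in simulated libraries where Lang-DTA equalled adult WT but for counting error. With young WT also set equal to adult WT, the simulated correlation was 0.769. With the adult WT counts split at random between the ratios, the lymphatic correlation was 0.205. It was 0.109 for age from male-called with genotype from female-called cells, 0.244 the other way round, and 0.424 without clusters 5 and 28. In blood endothelial cells the correlation was 0.379 and the covariance 0.019 over 3816 genes (simulated 0.055 and 0.001, and a correlation of 0.384 with both unchanged), with 0.361 for split counts and 0.244 and 0.388 across the sexes. The correlation was 0.278 in chondrocytes (simulated 0.141, and 0.646 with both unchanged; 0.178 for split counts; 0.063 and 0.191 across the sexes) and 0.211 in fibroblasts (simulated 0.117 and 0.408; 0.146 for split counts; 0.044 and 0.109). It lay close to the simulated value in gamma delta T cells (0.099, simulated 0.083 and 0.483; 0.052 for split counts) and in keratinocytes (0.070, simulated 0.049 and 0.421; 0.055 for split counts). In gamma delta T cells it turned to -0.076 for age from male-called with genotype from female-called cells.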

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

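Of the tests of the patterns in this part, only the one of transcript length for age was written down before its result was seen, and all others were chosen only after the results. The sex, cell weighting and doublet settings given with the remaining results were planned, but leaving out clusters was not. The gene lists were fixed before the data were examined.

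The first pattern is the wide difference of lymphatic endothelial cells in the Lang-DTA library, where the immediate early list lay at -1.139 and the same list in keratinocytes at 0.11, a difference of 1.249 that was not tested. Processing of the whole library could have shifted every class. The genes 2-fold apart in lymphatic cells had a median log2 ratio of 0.155 in the same direction in blood endothelial cells (748 genes, quartiles 0.039 and 0.245). In the other classes the median was 0.009 to 0.033, which argues against a shift of that size in every class. Most of the genes lay in the lymphatic direction in blood endothelial cells, so a smaller shift shared by the endothelial classes is left open. Cells or free RNA of another class could have entered the lymphatic gate. Of the 10 other named classes of this library and 7 unnamed clusters, the highest share of its own level reached in these cells was 3.245%. That was for an unnamed cluster of 21 cells led by haemoglobin and T cell genes, and the highest among named classes was 1.359%. These shares argue against free RNA of those classes and clusters. They do not test stray cells, because all libraries were clustered together and such cells would tend to join their own class. Nor do they test cluster 5, which held 74.4% of these cells and lies inside the class examined. Handling of the lymphatic sort of this pool alone remains possible, since the immediate early list was lower by -0.997 in lymphatic than in blood endothelial cells and the shortest genes lay 0.528 above the longest in lymphatic cells against 0.025 to 0.119 in the other classes, and a sort handled apart and a response of lymphatic endothelium to the lack of Langerhans cells cannot be told apart here. A second pool of Lang-DTA mice sorted together with littermates would separate them.

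The second pattern is a shift shared by all classes between the young and adult libraries, with Nmt1, Atp5k, Btg1 and Pabpc4 higher and Il31ra and Lars2 lower in adult WT in each of the 7 classes. Recovery of short cDNA could differ between libraries: the median transcript length was 2408 bases for the 75 genes higher in all classes, 2629.5 for the 6 genes lower in all classes and 3907 for all 3145 genes, but the smallest gap in log2 ratio between the shortest and the longest 315 genes was -0.002, in gamma delta T cells, and the largest 0.335, in chondrocytes. These genes reached, in the class where they were lowest, a median of 64.0% of the pooled level. They were chosen because they shifted by at least 1.5-fold in every class, which needs a measurable level in each. A high share therefore followed in part from the choice of genes, and it cannot decide on free RNA common to a library. Processing of the young library as a whole and a true change between 4 and 8 weeks cannot be told apart, since adult Lang-DTA lay at 0.949 of the way from young to adult WT, as either would give.

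The third pattern is MHC class II RNA in keratinocytes, with Cd74 at 22.9, 22.0 and 2.58 CPM in young WT, in adult WT and in adult Lang-DTA. If it were free RNA of Langerhans cells, Cd74 and Cd207 should stand in the ratio found in those cells. In adult WT keratinocytes the ratio was 28.63 (18.5 to 48.5 over cells drawn again) Cd74 UMIs per Cd207 UMI against 7.35 in Langerhans cells, which argues against this source alone. In young WT it was 6.35 (3.89 to 17.1) against 5.45, but 3 cells held 70 of the 85 Cd207 UMIs, so that this ratio mainly describes those cells. A biological source in keratinocytes was not tested.

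The remaining results drew attention because a list lay beyond its random lists on opposite sides in a pair of classes, and none of these differences was tested. The NF-kB list lay at 0.288 in chondrocytes and -0.25 in Langerhans cells for age, a difference of 0.538, and in Langerhans cells it was 0.01 in female-called cells. The same list lay at 0.128 in blood endothelial cells and -0.144 in chondrocytes for genotype, a difference of 0.272, and it reversed to -0.025 with cells weighted equally and to 0.042 in female-called cells, in turn. Cholesterol synthesis genes lay at 0.061 in keratinocytes and -0.32 in chondrocytes for genotype, a difference of 0.381, and in keratinocytes it was -0.003 with cells weighted equally. Proliferation genes lay at 4.177 in lymphatic cells and -0.911 in gamma delta T cells for genotype, a difference of 5.088, and they lay at 0.891 in lymphatic cells without clusters 5 and 28 and at 0.151 in gamma delta T cells with doublet calls kept, and at -0.076 there without the cycling cluster.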

How the results depend on the processing

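Lymphatic cells held 30611965, 8138277 and 24303585 UMIs in young WT, in adult WT and in adult Lang-DTA, and among the classes compared fibroblasts of adult Lang-DTA held the fewest (3309774). Each condition was 1 pool, so that no setting below measures differences between mice. Of 2305 list medians under other settings, 1740 stayed within their counting interval, 540 moved and 25 reversed. Of 1272 ratios of named genes, 971 stayed, 301 moved and 0 reversed. Named genes had to go the same way in both sexes, so the male-called, female-called and mean-of-sexes settings could not reverse them. Of 63 shares of immune cells, 45 stayed and 18 moved, and of 119 interquartile ranges of ratios, 63 stayed and 56 moved. Of 37 correlations along the age difference, 7 stayed, 29 moved and 1 reversed. For the values below the cause was not tested unless it is named. Medians are log2 ratios in lymphatic cells unless another class is named.

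With clusters 5 and 28 left out, a setting added after the data were seen, the age median of proliferation was -0.565. For genotype the interquartile range was 0.476, and medians were -0.138 (capillary identity), -0.117 (collector and valve), 0.195 (receptors and regulators), 0.013 (leukocyte trafficking), 0.5 (MHC class I), 0.582 (interferon), 0.891 (proliferation), -0.198 (Notch) and -0.447 (circadian clock), and 1.228 for the erythroid check list. The correlation along the age difference was 0.424. By construction this setting takes out 80.4% of the Lang-DTA lymphatic cells.

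At Leiden resolution 0.5 migratory dendritic cells made up 0.654%, 0.34% and 2.033% of immune cells in young WT, adult WT and Lang-DTA, and at resolution 2.0 they made up 0.658%, 0.341% and 2.053%. Gamma delta T cells at resolution 2.0 made up 48.114%, 54.115% and 64.158%.

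In male-called cells only, shares were 20.859% for Langerhans cells in young WT, 57.106% for gamma delta T cells in adult WT, 4.218% and 5.821% for macrophages in young WT and Lang-DTA, and 3.834% and 1.884% for migratory dendritic cells in young and adult WT. Age values were 0.41 for the interquartile range and medians of -0.401 (junction), 0.218 (interferon), 0.543 (immediate early), -1.651 (proliferation), -0.659 (basement membrane) and 0.523 (glucocorticoid), with reversals to 0.27 and 0.926 for MHC class II in fibroblasts and keratinocytes and to -0.03 for lymphangiogenic ligands in fibroblasts. Genotype values were 1.022 for the interquartile range and medians of -0.961 (capillary identity), 0.628 (MHC class I), 0.952 (interferon), 3.696 (proliferation) and 1.365 (circadian clock), with a reversal to -0.306 for MHC class I in keratinocytes.

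In female-called cells only, shares were 17.397% for Langerhans cells in young WT, 46.603% for gamma delta T cells in adult WT and 7.355% for macrophages in young WT. Age values were 0.396 for the interquartile range and 0.289 for immediate early genes, with reversals to 0.01 for NF-kB in Langerhans cells, -0.012 for interferon and -0.071 for NF-kB in blood endothelial cells, and -0.03 for hypoxia in chondrocytes. Genotype values were 1.022 for the interquartile range and -0.961 for capillary identity, with reversals to 0.042 for NF-kB in chondrocytes and 0.068 for proliferation in keratinocytes. With the mean of both sexes, the genotype median was -0.961 for capillary identity and -0.096, reversed, for MHC class I in keratinocytes.

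With a list floor of 50 CPM, which leaves fewer genes, age medians were -0.346 (proliferation) and -0.785 (basement membrane), with a reversal to -0.025 for hypoxia in Langerhans cells, and genotype medians were -0.643 (receptors and regulators), 0.979 (MHC class I), 1.808 (proliferation) and 1.617 (circadian clock). With no floor, age medians were -2.531 (proliferation) and -0.568 (fibrillar matrix), with a reversal to -0.021 for the macrophage check list in Langerhans cells, and the genotype median of Notch was -0.606.

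With doublet calls kept, proliferation was -1.374 for age and 2.932 for genotype, and in gamma delta T cells it reversed to 0.151 for genotype. The genotype interquartile range was 0.991, and the keratinocyte check list in fibroblasts reversed to -0.07 for age and 0.612 for genotype. With free RNA subtracted, that list reversed to -0.46 and 0.333, and the age median of fibrillar matrix was -1.147. With the stricter cell filter, medians were 0.475 (immediate early, age), -0.948 (capillary identity, genotype) and 4.558 (proliferation, genotype).

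With cells thinned to a fixed depth, the interquartile range was 0.379 for age and 0.908 for genotype, age medians were 0.503 (immediate early) and -1.797 (proliferation), and genotype medians were -0.895 (capillary identity), -0.361 (receptors and regulators) and 0.704 (MHC class I). With median-of-ratios scaling, which moves all ratios of a class alike, age medians were -0.174 (junction), 0.423 (MHC class I), 0.52 (interferon), 0.556 (immediate early) and -0.447 (basement membrane). Genotype medians were -1.019 (capillary identity), -0.985 (collector and valve), -0.643 (receptors and regulators), -0.543 (leukocyte trafficking), 0.711 (MHC class I), -1.233 (immediate early) and -0.917 (Notch).

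With cells weighted equally, age medians were 0.487 (immediate early) and -1.354 (proliferation). The genotype interquartile range was 0.894 and medians were -0.795 (capillary identity), -0.725 (collector and valve), -0.434 (receptors and regulators), -0.355 (leukocyte trafficking), 0.726 (MHC class I), -0.984 (immediate early), 3.101 (proliferation) and -0.717 (Notch). Reversed for genotype were the erythroid check list in lymphatic cells (0.043), NF-kB in blood endothelial cells (-0.025) and cholesterol synthesis in keratinocytes (-0.003).

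Along the age difference, the lymphatic correlation was 0.109 for age from male-called with genotype from female-called cells and 0.244 the other way round, 0.29 for genes at 20 CPM or more and 0.23 for genes at 100 CPM or more. In gamma delta T cells it reversed to -0.076 for age from male-called with genotype from female-called cells.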

Other observations

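Gene lists of other cell types served as a check on free RNA in lymphatic cells. Keratinocyte genes had a median log2 ratio of 1.499 for age and -0.99 for genotype, and erythroid genes 1.15 and -0.81. With clusters 5 and 28 left out, the genotype medians were -1.41 and 1.23. In young WT, adult WT and Lang-DTA in turn, fibroblast genes summed to 41.3, 38.3 and 16.3 CPM, macrophage genes to 161, 193 and 82.5 CPM, granulocyte genes to 0.10, 0.25 and 0.21 CPM, and cartilage and muscle genes to 1.21, 0.74 and 0.66 CPM.

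The erythroid list also differed between libraries in other classes, at 36.2, 2.9 and 101.3 CPM in gamma delta T cells and 16.0, 96.9 and 27.3 CPM in blood endothelial cells of young WT, adult WT and Lang-DTA in turn.

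Male-called cells made up 53.6% of cells with a call in young WT, 51.8% in adult WT and 33.4% in Lang-DTA, from pools with 5 of 8, 6 of 10 and 4 of 10 male mice. In lymphatic cells the shares were 50.1%, 40.7% and 37.1%. Cells with at least 1 Cd207 UMI made up 1.23% of keratinocytes in young WT, 0.844% in adult WT and 0 of 3000 in Lang-DTA, which allows a share of up to 0.1% (3 counts of the total).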
